A study of Rattus norvegicus with 20 samples.

How the data were processed

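Left-ventricle RNA of 20 rats was hybridised to Applied Biosystems Rat Genome Survey arrays (version 1.0), read by chemiluminescence on the AB 1700 system. Per the labels, 20 mg of tissue was used, and RNA with an integrity number above 8 was analysed. Each array's deposited table holds a signal intensity per spot, which the scanner software wrote, with bit flags and a signal to noise score per spot, per the file headers. The tables also hold the software's own normalized intensity, which from the values is the signal divided by 1 of 2 factors per array, 1 for each part of the array. Signals below noise carry the spot's own noise estimate in place of a signal, which was so for 100% of the spots with that flag, and these made up 30.9% to 37.9% of an array. Such values bound a level and do not measure it.

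Per the series' design text, the authors removed flagged and control spots, quantile normalized the arrays, took logs, allowed at most 20% missing values and filled in missing values by LSimpute Adaptive, with J-Express Pro version 2.8. They tested genes with Rank Product and gene sets with GSEA, and their results were not used here. The scanner software's version and its background steps are not given in the sources used here. The authors' deposited value table holds log2 values of 26851 probes, the same number as kept here. For 19 arrays its columns have the same rank order as the scanner signal, so its scale is log2 of quantile-normalized signal, with no centring of genes. Column medians lay between 10.45 and 10.47, except 10.57 for LRT trained 1. That column has 1468 empty cells, a Spearman correlation of 0.983 with the scanner signal, and 474 values more than 1 log2 from the recomputed ones. The name inside that array's scanner file carries neither its replicate number nor its training state, and the labels were followed. The value table was used as an alternative.

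From the scanner signal, control spots were left out, spots with a flag of 5000 or more were set to missing (92 to 382 per array), arrays were quantile normalized on the log2 scale, and probes missing on more than 20% of the arrays were dropped. Nothing was imputed. All 20 arrays entered 1 fit of 4 group means in limma 3.58.1 (lmFit and eBayes) in R 4.3.3, with Benjamini-Hochberg adjustment over all probes and a threshold of adjusted p 0.05. A probe counted as detected on an array at a signal to noise of 3 or more. The comparisons were HRT against LRT in sedentary and in trained animals, trained against sedentary in HRT, in LRT and averaged over the lines, and the interaction. The design, the groups, the gene lists and a list of other settings to try were fixed before the data were examined. The design text gives 5 rats per group. The line averaged over the training states, settings that leave out arrays standing apart and fits within a scan day were added after the data had been seen.

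Genes were named from unversioned RefSeq accessions, or identifiers listed as synonyms, in a table of rat genes. Of 57 accessions 34 matched, and 1 of 26800 rCG identifiers matched. The rule for named genes took genes with exactly 1 symbol, called, and detected on at least 4 of 5 arrays of a compared group, up to 10 in each direction. With fewer than 5 in a direction, those with the smallest unadjusted p were added up to 5 and are given as not passing. Of the genes that this rule names, 1 is not reported here. Gene set tests were planned and could not be run, since no list had 5 measured members.

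The fit was tested on simulated arrays with the real probe means and spreads. Of 26851 probes, 100 were changed by 1 and 100 by 2 on the log2 scale in HRT sedentary against LRT sedentary. It recovered 43% and 81%, with 2 unchanged probes among 126 calls. Rank Product, written for this work with every pair of arrays and 100 permutations, recovered 9% and 90% and called 107 unchanged probes. With 1 spread for all probes it called 4 unchanged probes among 125, so with unequal spreads it called more unchanged probes. Which of its calls on the real arrays are false was not tested. The simulated values were drawn independently, with no scan day effect and no arrays standing apart. The rates of both methods therefore need not hold on the real arrays.

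Scan day was read from the scanner files. The design text says that groups were balanced over 2 hybridisation days, while 9 of 10 HRT arrays were scanned on day 1 and 9 of 10 LRT arrays on day 2. Scan day was therefore used as a block and within days. Pairs of arrays had correlations from 0.931 to 0.987 over detected probes, and no 2 arrays held identical values. The other settings were other scalings, flag filters, an offset of 50, detected probes only, blocks, array weights, eBayes with trend and robust settings, a log2 fold change of 0.5 or more, Rank Product, and leaving out each array. Figures were drawn with matplotlib 3.10.9.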

Results

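RNA from the left ventricle of the heart was measured on 20 one-colour expression arrays, 1 for each of 20 female rats aged 12 months. The rats came from generation 7 of 2 lines bred from a genetically mixed stock. High responders (HRT) were selected for a large gain in treadmill running capacity after exercise training, and low responders (LRT) for a small gain. Each line had 5 trained and 5 sedentary animals, so there were 4 groups of 5. Between 47.5% and 58.0% of the probes were detected on an array, and the number of arrays limits the precision of every comparison. Of 26857 probes, 26851 were tested and 13911 were detected on at least 4 of 5 arrays of 1 or more groups. The files and the gene table used here pair 35 probes with a gene symbol, for 34 genes. The other probes carry identifiers of an older rat genome assembly (rCG), which the files do not pair with gene names, so at most 2 identifiers in each direction are given for a comparison.

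The first comparison asked how the ventricles of the lines differed without training. In sedentary animals, limma called 5 probes higher and 3 lower in HRT than in LRT, and 1 of the 3 was detected on 0 of 20 arrays, so its signal does not measure a level. The probe for rCG50998 was higher in HRT by 3.93 on the log2 scale (SE 0.57, n = 5 and 5, limma adjusted p = 0.0186). Its normalized log2 signal was 12.42 ± 1.00 (SD, n = 5) in HRT and 8.49 ± 0.60 (SD, n = 5) in LRT, where it was detected on 1 of 5 arrays, so its level there is bounded and not measured. The probe for rCG48171.1 was higher in HRT by 3.83 (SE 0.62, limma adjusted p = 0.0414). Its SE draws on the spread within all 4 groups. The SD was 0.27 in sedentary HRT, 0.20 in sedentary LRT and 2.03 in trained LRT animals, which are outside this comparison. The probes for rCG23489 and rCG41615 were lower in HRT, with log2 fold changes of -1.93 (SE 0.29, limma adjusted p = 0.0186) and -1.76 (SE 0.29, limma adjusted p = 0.0414). None of the 8 called probes had overlapping values between the groups. At an unadjusted p under 0.05 there were 1264 probes, where 1343 would be expected by chance.

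The line difference was nearly the same split as the day of scanning. Day 1 held 9 HRT arrays and 1 LRT array, and day 2 held 9 LRT arrays and 1 HRT array. With scan day as a block limma called no probe between the sedentary lines (1132 at an unadjusted p under 0.05), and Rank Product, without a block, called 83 (28 higher and 55 lower). The difference at rCG50998 was then 4.65 (SE 0.79) and that at rCG48171.1 was 4.84 (SE 0.83). The SE grew at all 8 probes, and the share of the log2 fold change that was kept ran from 0.81 to 1.26. These shares rest on the 1 array of each line that was scanned with the other line. Day 2 held 1 sedentary HRT array, too few for a comparison within a day. The limma count was 0 when any of 6 sedentary arrays was left out (HRT sedentary 1, 2, 3 or 5, LRT sedentary 2 or 5), and 0 without the 3 sedentary arrays that stood apart from the rest.

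The same question was put to the trained animals, which were other rats. The probe for rCG50998 was again higher in HRT, by 4.51 on the log2 scale (SE 0.57, n = 5 and 5, limma adjusted p = 0.00615). It was detected on none of the 5 LRT trained arrays, so its level there was not measured. Taking the signals of those arrays as they stand, the difference was 22.8-fold, which is an estimate and not a lower bound. The probe for rCG31045 was lower in HRT, with a log2 fold change of -1.78 (SE 0.24, limma adjusted p = 0.00995). These were the 2 probes called, and 1708 had an unadjusted p under 0.05. With scan day as a block limma called 0 (1585 at an unadjusted p under 0.05), and with only the 10 trained arrays in the fit 0 (1714), while Rank Product called 53. With the block the differences were 5.22 (SE 0.79) at rCG50998 and -1.66 (SE 0.35) at rCG31045, so the SE grew at both. Day 1 held 1 trained LRT array, too few for a comparison within a day.

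Sedentary and trained animals gave independent estimates of the line difference. Of the 8 probes called in sedentary animals, 6 had the same sign in trained animals, and 4 of these had an unadjusted p under 0.05. Probes at an unadjusted p under 0.05 in both comparisons were higher in HRT in 45 cases and lower in 81, where independent lists would share 16.7 and 23.3. Both lists use the same error variance per probe, which by itself raises the overlap, so these are low reference values. Across 26851 probes the log2 fold changes had a Pearson correlation of 0.138, and over detected probes of 0.275. Probes are not independent replicates. Both estimates share the imbalance of scan days between the lines. At the 8 probes, LRT trained 3, 4 and 5 had median positions of 0.83, 0.77 and 0.74 between the sedentary means (0 at LRT, 1 at HRT), and LRT trained 1 and 2 of 0.37 and 0.16. Averaged over the training states, a comparison added after the data had been seen, 6 probes were higher and 8 lower in HRT. With scan day as a block 1 was called, rCG50998, at 4.93 (SE 0.69, limma adjusted p = 0.0335). It was no longer called without HRT sedentary 2 (3.67, SE 0.91, limma adjusted p = 0.143) or without LRT trained 1 (6.20, SE 0.91, limma adjusted p = 0.0922). The probe was undetected on most LRT arrays, so these differences rest on a level there that was not measured.

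**Figure D1:**
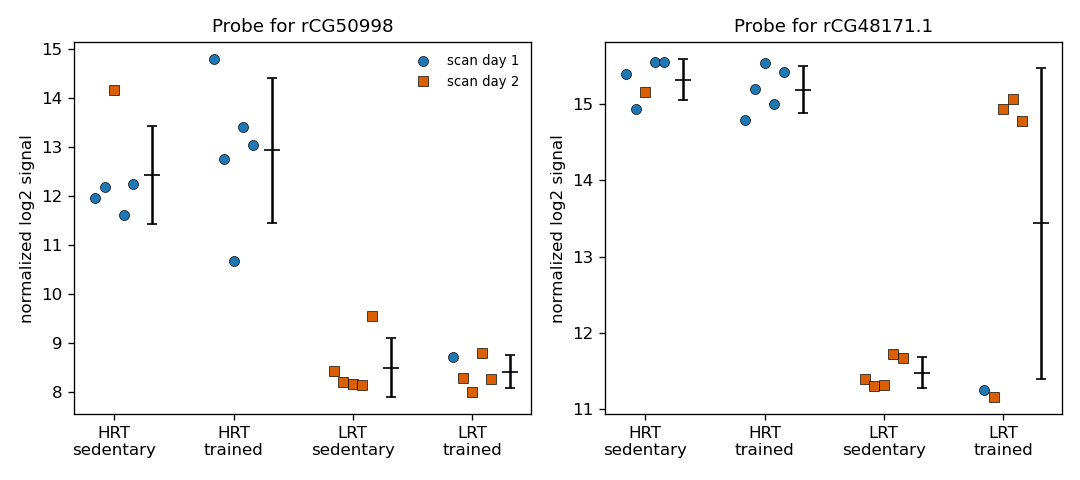
Normalized log2 signal (vertical axis) of the probes for rCG50998 and rCG48171.1 on each array, by group; circles were scanned on day 1 and squares on day 2, and bars show the mean ± SD (n = 5). At rCG50998 the lowest HRT array is at 10.67 and the highest LRT array at 9.55. At rCG48171.1 LRT trained 3, 4 and 5 lie at 14.93, 15.06 and 14.77, near the HRT arrays (14.79 to 15.55), and LRT trained 1 and 2 at 11.26 and 11.16.

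In low responders limma called 9 probes lower after training and none higher, while Rank Product called 32 lower and 18 higher. The largest fall was at the probe for rCG20898.1, whose log2 fold change was -3.78 (SE 0.58, n = 5 and 5, limma adjusted p = 0.0146), 13.7-fold lower in trained rats. Its normalized log2 signal was 17.60 ± 0.36 (SD, n = 5) in sedentary and 13.82 ± 1.07 (SD, n = 5) in trained animals. The probe for rCG50808 changed by -3.59 (SE 0.52, limma adjusted p = 0.0146). The smallest of the 9 falls was 2.13-fold. All 9 probes were bright, with mean log2 signals of up to 17.77, were detected on all 20 arrays, and had no overlap between trained and sedentary LRT animals. At an unadjusted p under 0.05 there were 903 probes, against 1343 expected by chance.

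With scan day as a block 8 of the 9 were called. Within day 2, with 4 trained and 5 sedentary animals, limma called 0 (smallest adjusted p 0.0664, 1340 at an unadjusted p under 0.05), and the median log2 fold change of the 9 probes was -1.48 (-1.53 over all arrays). Leaving out LRT trained 1 left 1 call, LRT trained 4 or LRT sedentary 5 left 3, and LRT sedentary 4 left 4 (1 higher and 3 lower). Without the 3 sedentary arrays that stood apart there were 4 calls.

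Training in high responders called no probe with limma (smallest adjusted p 0.249), while 1896 probes had an unadjusted p under 0.05 against 1343 expected by chance, and Rank Product called 13. Within day 1, with 5 trained and 4 sedentary arrays, limma called 0 (1188 at an unadjusted p under 0.05). The 9 probes lowered in LRT were all lower in trained than in sedentary HRT animals, with log2 fold changes from -0.58 to -2.46 and a median of -0.93. None passed over all probes (adjusted p from 0.249 to 0.704), and adjusted over the 9 alone all 9 did. The 9 were chosen for their change in LRT, in a fit whose error variance also drew on the HRT arrays. The mean deviation of the 9 probes was -0.53 ± 0.28 (SD, n = 5) in trained and 0.58 ± 0.43 (SD, n = 5) in sedentary HRT animals, a difference of -1.10 (two-sided exact permutation p = 0.00794, the smallest that 5 against 5 can give). Within scan day 1 the difference was -1.13 (exact permutation p = 0.00794, the smallest that 5 against 4 can give). Over the 6 probes called in a fit of the LRT arrays alone, a choice made after seeing the data, the difference in HRT was -1.25 (exact permutation p = 0.00794). In LRT, where the probes were chosen, the difference of the 9 was -2.08.

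**Figure D2:**
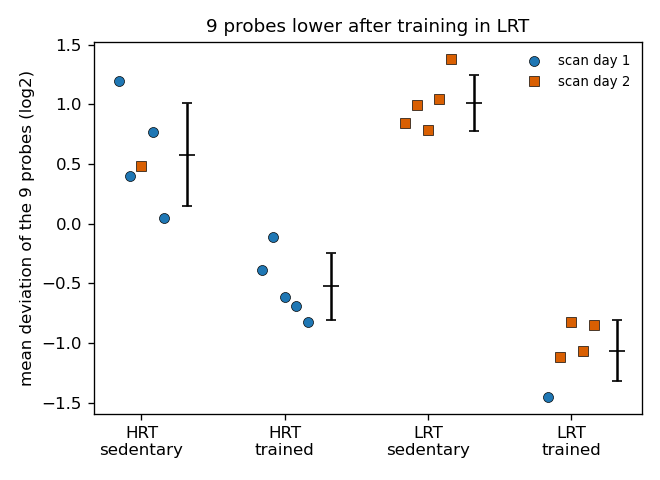
Mean deviation (log2, vertical axis) of the 9 probes from their mean over all arrays, for each array by group; circles were scanned on day 1 and squares on day 2, and bars show the mean ± SD (n = 5). The mean of trained minus that of sedentary animals is -1.10 in HRT and -2.08 in LRT.

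Averaged over the lines, limma called 9 probes lower after training, the same 9 as in LRT, and none higher. The average contains the LRT change, from the same arrays and the same fit, so this overlap is partly built in. The probe for rCG20898.1 changed by -3.12 (SE 0.41, limma adjusted p = 0.00375) and that for rCG50808 by -2.36 (SE 0.37, limma adjusted p = 0.0155). With scan day as a block 8 were called. At an unadjusted p under 0.05 there were 1787 probes, 896 higher and 891 lower. Without the 3 sedentary arrays that stood apart 5 were called.

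Whether training acted differently in the lines was tested as an interaction. With limma no probe passed (smallest adjusted p 0.629), and 1008 had an unadjusted p under 0.05, against 1343 expected by chance. No other tool was run for it. Across all probes the training responses of the lines had a Pearson correlation of 0.0893, and of 0.184 over detected probes. Probes at an unadjusted p under 0.05 in both lines were higher in 23 cases and lower in 54, where independent lists would share 15.2 and 16.7. These lists too share the error variance of each probe, which by itself raises the overlap.

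None of the 34 named genes passed, adjusted over all probes in any comparison, or over the named probes alone in the comparisons other than the line averaged over training, and 11 of their 35 probes were detected. Cebpb, a transcription factor of the C/EBP family, had a log2 fold change after training of -0.72 (SE 0.21, limma unadjusted p = 0.00308, adjusted over the named probes 0.108) in LRT and -0.24 (SE 0.21) in HRT, and the difference between the lines was not past the threshold (0.48, SE 0.30). Averaged over the lines its change was -0.48 (SE 0.15, limma unadjusted p = 0.00475). Six3, a homeobox transcription factor, was 0.41 (SE 0.19, limma unadjusted p = 0.0446) in HRT against LRT sedentary animals, and -0.38 (SE 0.19) after training in HRT. In trained animals Itgae, the integrin alpha E subunit, was at -0.47 (SE 0.19, limma unadjusted p = 0.0272) and Hbb-b1, an adult beta globin, at -2.25 (SE 1.01, limma unadjusted p = 0.0393) in HRT against LRT. Hbb-b1 differed widely between animals, from a log2 signal of 13.13 in HRT trained 3 to 19.75 in LRT trained 1. Kcnip2, a subunit of the transient outward potassium channel of heart muscle, had 2 probes, with log2 fold changes of 0.73 (SE 0.57) and 0.50 (SE 0.39) after training in HRT. The first was low in HRT sedentary 1 and 2 (12.44 and 13.66, others 15.08 to 15.37), and its log2 fold change was -0.12 without the 3 sedentary arrays that stood apart. Atf4, a transcription factor of the stress response, changed by 0.08 (SE 0.14) after training in HRT. Ramp2, an accessory protein of the adrenomedullin receptor, changed by -0.10 (SE 0.16) in HRT and 0.06 (SE 0.16) in LRT. Rtn3, a reticulon of the endoplasmic reticulum, was at 0.25 (SE 0.39) after training in LRT, and Tpra1 at 0.03 (SE 0.16) in HRT against LRT sedentary animals.

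The 44 gene lists fixed for heart muscle, metabolism, vessels, matrix and other cell types hold 995 distinct genes, and 3 of these have a named probe. Kcnip2 stands for the ion channels, Mmp2 for the extracellular matrix and Hbb-b1 for the red blood cells, and no list reaches the 5 measured members set for a test. Mmp2 was not detected on enough arrays of any group to be compared. The 12 genes fixed in advance as markers of cardiac load and metabolism have no named probe here and were not analysed.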

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

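In this part the tests of the 9 probes, the line probes and the hybridisation controls were chosen after their results were seen, as was the comparison averaged over the training states. The counts over random splits were planned, except for that comparison.

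Across 84 groups of 5 arrays (21 measures), 5 had 1 array far from the others, where chance gives about 1 in 20, or 4.2. The gap over the range was 0.751 for 1 Kcnip2 probe in HRT trained 1 (14.28, others 15.04 to 15.30) and 0.729 for Itgae in LRT sedentary 1 (14.29, others 13.64 to 13.81). At rCG50998 it was 0.754 in HRT sedentary 2 (14.15, others 11.60 to 12.23) and 0.794 in LRT sedentary 4 (9.55, others 8.14 to 8.43). At rCG50808 it was 0.712 in HRT sedentary 4 (15.33, others 12.66 to 13.43).

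Control spots, which enter no comparison, differed between scan days. The hybridisation controls had a median signal of 77394.5 to 109538 on the 10 arrays of day 1 and 340974 to 424263 on the 10 of day 2, a ratio of means of 3.87. The cause was not tested. Other controls overlapped between the days, from 139963 to 351650 on day 1 and 180627 to 377397 on day 2 for the reverse transcription controls, and from 46082 to 90983 and 49946 to 109986 for the in vitro transcription controls.

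The 9 probes lowered by training are the first pattern weighed. A scan day effect would bring their change towards 0 within a day, and in HRT within day 1 the median log2 fold change was -1.01. The 3 sedentary arrays that stood apart are argued against as the cause in HRT, where the median without them was -0.97. In LRT the medians were -1.48 within day 2 and -1.71 without those arrays. The 9 probes were chosen on nearly the same LRT arrays, so the LRT medians could hardly have come near 0. Selection in LRT alone would leave no change in HRT, where the exact permutation p was 0.00794, also for the 6 probes called in a fit of the LRT arrays alone (-1.25). The fall may follow training, or an untested difference in handling, feeding or time of sampling between trained and sedentary rats, which stays open.

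A difference between the lines was tested for these probes. The mean deviation fell more in LRT, by a difference of 0.97 (two-sided exact permutation p = 0.00208, dealing line labels anew within trained and within sedentary rats; fry, the rotation test of limma, gave 0.00119). The probes were chosen for their fall in LRT, which by itself favours a larger value there, so neither value shows a different response. No single probe passed the interaction test.

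The line difference is the second pattern. A difference wholly absent from other animals is argued against for the 8 probes as a set. In trained rats they had a median of 0.68 in the direction seen in sedentary rats. There 6 had the same sign, 4 of these at a limma unadjusted p under 0.05. That median is smaller in size than the log2 fold change of each of the 8 in sedentary rats, where they were chosen. Scan days were split between the lines in trained rats too, so a scan day effect would also recur there. Line and scan day cannot be told apart, because 1 array of each line was scanned with the other, and that of LRT (LRT trained 1) has its day and level from a scanner file that may not belong to it: rCG50998 kept a difference of 4.93 with scan day as a block, averaged over training (limma adjusted p = 0.0335), but was not called without HRT sedentary 2 (3.67, SE 0.91) or without LRT trained 1 (6.20, SE 0.91). The other 8 probes called in sedentary or trained animals kept a median share of 1.06 and were not called with the block, and the 2 arrays lay at median positions of 0.14 (LRT trained 1, range -0.50 to 1.55) and 0.04 (HRT sedentary 2, range -0.42 to 0.53), where 0 is the own line, 1 the other, and the 1.55 is of a probe not detected on any array. HRT sedentary 2 was among the arrays on which the probes called in sedentary animals were chosen, which by itself draws it towards its own line. The shares kept rest on HRT sedentary 2 and LRT trained 1, so they do not decide on scan day. What would decide these questions was set after these values were seen. The differences at rCG50998 are not exact, since its level in LRT was not measured on most arrays. A sequence variant under a probe, which could change its signal without a change in RNA, was not tested.

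Among 100 splits of the animals, the real one and others drawn at random, the real split gave the most calls for several counts. These were the sedentary lines (8 calls, highest other split 2, 1 of 100 as large) and LRT training (9 calls, highest other split 6, 1 of 100 as large). They were also training averaged over the lines (9, highest other 1, 1 of 100) and the line averaged over training (14, highest other 3, 1 of 100). Chance is argued against for these counts, not for each probe called. The share of 1 of 100 is the smallest that 100 splits can give, and it was not adjusted over the counts tried. Leaving out single arrays gave as few as 0 calls between the sedentary lines and 1 in LRT training. For the trained lines (2, highest other 2, 2 of 100, the real split and 1 other) chance is not excluded. Another split gave as many calls there, and 0 were called with only the trained arrays in the fit. For HRT training (0 calls, highest other 2) and the interaction (0, highest other 1) all 100 splits give as many by construction, so the splits decide nothing there. Random splits mix the scan days, which the lines do not, so for the lines they leave scan day open: with it as a block the counts were 0 in sedentary animals, 0 in trained animals and 1 averaged over training. The correlation of the line differences was 0.138 (highest other 0.130, 1 of 100) and that of the training responses 0.0893 (highest other 0.145, 4 of 100).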

How the results depend on the processing

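Settings without the arrays that stood apart, within a scan day, combining detected probes with a day block, and all settings of the line averaged over training and of the 9-probe score, were chosen after seeing the data. No result reversed, and the causes of the changes below were not tested. A bracket such as fewer arrays or fewer tests names what else differed in that setting, not a tested cause. HRT training stayed at 0 calls in every setting except Rank Product (13) and the interaction at 0 except without LRT sedentary 4 (1). Calls between the sedentary lines (8) became 5 with any flag missing, 0 with scan day as a block, also over detected probes, 2 with the replicate block, 1 with array weights, 0 without the 3 or the 4 arrays that stood apart (fewer arrays) and 83 with Rank Product (28 higher, 55 lower, against 5 and 3), and on scan day 2 only 6 (6 higher, 0 lower, 1 of the 8 kept), with a lone HRT array assumed to vary like the other group. LRT training (9) gave 5 with the replicate block, 4 without the 3 arrays, 5 without the 4, 0 on scan day 2 only (fewer arrays) and 50 with Rank Product (18 higher, 32 lower); median scaling gave 2 higher and 9 lower, against 0 and 9. The trained lines (2) gave 4 with an offset of 50, over detected probes, with trend and robust, and without the 3 arrays, 1 with the replicate block and without the 4 arrays, 0 with scan day as a block, also over detected probes, and on only the arrays compared, 27 on scan day 1 only (its lone LRT array is assumed to vary like the other group, so this does not test the line difference) and 53 with Rank Product. Training averaged over the lines (9) gave 14 over detected probes (fewer tests), 18 with trend and robust and 5 without the 3 arrays. The line averaged over training (14) gave 27 with the software's normalized signal (6 higher, 21 lower, against 6 and 8), 30 over detected probes and with trend and robust, 1 with scan day as a block, also over detected probes, 65 with that block and no HRT sedentary 2, 0 with it and no LRT trained 1 (each then resting on 1 crossing array), 3 without the 3 arrays and 6 without the 4. The correlation of line differences (0.138) was 0.263 with median scaling, 0.259 with the software's signal, 0.215 with any flag missing and 0.275 over detected probes. It was 0.551 with scan day as a block and 0.604 with detected probes too, where both estimates share 1 day effect, which by construction raises it. That of training responses (0.0893) was 0.173 with any flag missing, 0.184 over detected probes, 0.177 with the day block added, 0.0237 without the 3 arrays and 0.0219 without the 4. Leaving out each array gave 0 to 16 calls between sedentary lines (18 of 20 moved; 14 higher and 2 lower without LRT sedentary 1), 1 to 10 in LRT training, 0 to 1 in the interaction, 1 to 3 between trained lines (1 without LRT trained 5, HRT trained 2 or HRT trained 5), 8 to 12 for averaged training, 8 to 31 for the averaged line, correlations of 0.0988 to 0.172 and 0.0345 to 0.114, and a 9-probe score in HRT of -1.24 to -0.95. The replicate numbers do not pair the animals: 30 same-numbered pairs had a mean correlation of 0.00901, 5 over 0.1, and the replicate block changed no other call count by over 1.5 times. The printed probes kept their sign in 356 of 356 settings and their call in 255. The named genes were called in 0 of 1818 settings and changed sign in 84. The 8 alternatives for gene lists were not run, since no list could be tested. Low signal over background limits what dim probes show.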

Other observations

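The tests in this part were chosen after the results were seen.

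Some probes fell on 2 separate levels among the animals. Of 13849 detected probes with a value on every array, 24 had a gap of 1.5 or more on the log2 scale with at least 3 arrays on each side, and 0 of them split the lines exactly. The largest gap was 5.33, at rCG48616.1, with 10 arrays on each side and animals of both lines on both. A group of 4 probes divided the arrays identically, setting LRT sedentary 2, 3, 4 and 5 and LRT trained 1 and 2 against the other 14. Another 2, 1 of them for rCG48171.1, gave that split with LRT sedentary 1 added to the 6.

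These shared splits are the third pattern weighed, and made 7 pairs of probes with the same split, while dealing each probe's levels to the arrays at random gave at most 1 pair in 1000 draws, so independent levels are argued against. A wrong line label on LRT trained 3, 4 and 5 can be neither excluded nor shown, since probes go both ways. The 8 probes called between the sedentary lines were chosen on the sedentary means, which by itself draws other LRT arrays away from 0. They include rCG48171.1, which has a shared split. At the 8 the median positions of the 3 arrays were 0.83, 0.77 and 0.74 (0 at LRT, 1 at HRT), and those of LRT trained 1 and 2 were 0.37 and 0.16. At rCG41615, also among the 8, the 3 arrays lay at 11.70, 12.26 and 12.09 (HRT sedentary 11.67 to 12.18). Against a wrong label, their highest log2 signal at rCG50998 was 8.80 and the lowest HRT array was at 10.67. Another of the 24 probes (gap 2.59) set all 5 LRT trained arrays apart from all 10 HRT arrays. At rCG31045, chosen partly on the LRT trained arrays, the 3 lay at 12.27, 12.73 and 12.84 (HRT up to 11.77). Variants that still segregate in the LRT line were not tested, since the positions of the probes in the genome were not used here.

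Several arrays stood apart from their groups. The first 3 principal components of the same 13849 probes held 15.1%, 14.8% and 8.79% of the variance. HRT trained 1 lay at 81.9 on the first, and 186 of its probes were over 2 log2 from the group mean, where no other array had over 82. LRT sedentary 1 (55.4), HRT sedentary 1 (32.8) and HRT sedentary 2 (32.8) lay highest on the second. The same 3 arrays had the lowest values of the other Kcnip2 probe, at 12.15, 12.44 and 13.66. These are the 3 sedentary arrays left out in the settings above, a choice made after the data were seen. By probes over 2 log2 from the group mean the order differs. HRT sedentary 2 had 16, and HRT trained 3, which was not among the arrays left out as standing apart, had 82.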
